A study of Mus musculus with 4 samples.

How the data were processed

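RNA came from the amygdala of NpyCre/+;TRAPlox/lox mice, with IP and input RNA of 3 mice pooled per library and 200 ng of RNA used, per the series' design text. There were 2 IP and 2 input libraries, made with a TruSeq RNA kit per the labels' protocols and sequenced as 100 bp single-end reads per the design text. Strand-specific counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart. Reads were aligned with TopHat at default settings against mm10 with the iGenomes UCSC annotation, per the design text and the submitters' processing notes, which give no tool versions. The deposited values are Cufflinks gene-level FPKM for each library, made by the authors, with lower and upper confidence limits and a status, per the file headers. No scaling between libraries is recorded. The authors' Cuffdiff test was not used here.

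Groups and replicate numbers were taken from the sample titles. The title of IP replicate 2 disagrees with its source description, which gives replicate 1, and the title was followed. Each IP had a corresponding input from the same pooled mice per the design text, so the numbers were taken to pair the samples. The deviations from the group means of IP replicate 1 and input replicate 1 correlated at 0.161 across genes. The replicates were checked for duplication. No values at FPKM of at least 5 were identical, and the confidence intervals lay apart for 10.0% of genes between the input libraries and 14.9% between the IP libraries.

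Each library listed 24490 entries for 23991 symbols, and the 8 entries with a failed status and 1275 entries with small RNA names were left out. This pattern of names also removed Mirg. Where a symbol had several entries, the one with the highest mean was kept. Genes with FPKM of at least 1 in at least 2 libraries were tested, 12417 in all. Values were transformed as log2(FPKM + 1), so that fold changes of low genes are understated, and tested with lmFit and eBayes with a trend in limma 3.58.1 (R 4.3.3), without a block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. FPKM are not counts, and no count test was used. Fold values in words are ratios of mean FPKM, except in the 2-fold criterion, which is a log2 change of at least 1 on the transformed values. The p-values rest on 2 pools per group. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Coordinates are those of the files (mm10), written 1-based. Transcript lengths came from GENCODE transcripts matched by symbol, or by a RefSeq synonym, for 99.3% of the genes tested. The longest protein-coding transcript of a gene was taken, or the longest of any kind where none was protein-coding.

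The 23 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists. Of the 23, 4 passed upward and 9 downward, and 0 passed with an estimated correlation. With fry, which tests the balance of direction within a list and compares it with no other genes, 19 passed. Estimating the correlation leaves camera with the 2 residual degrees of freedom of the libraries. The Npy/Sst list, with an estimated correlation of 0.017, went from an unadjusted p of 0.000135 to 0.0661 (camera). Failing that test thus does not by itself show that correlation between genes accounts for a result. Among the lists that passed at 0.01, the estimated correlation ran from -0.047 (endothelial) to 0.74 (oligodendrocyte), with 0.373 for the GABAergic list. Where the estimate lies above the preset 0.01, the camera p at 0.01 may be too small. Fry added the other interneuron, pan-neuronal and peptide processing lists (upward) and the amygdala peptide, feeding receptor and insulin signalling lists (downward). The design, the lists, the alternatives named in the plan and the rule for named genes were fixed before the data were examined. That rule took a set of fixed genes (Npy, Rpl10a, Insr, Lepr, Npy1r, Npy2r, Npy5r, Sst, Gad1, Slc17a7, Crh and Nr3c1), the 10 largest changes in each direction among genes past the threshold whose groups did not overlap, without predicted genes, and up to 4 members of each list. A gene that this rule takes is not reported here. The repeat of the 10 largest changes among genes above 0 in all 4 libraries was added after the data were seen, as were the settings without genes listed at 0, with a correction for transcript length and with a 2-fold criterion. Other genes named in the text were chosen after their values were seen.

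Alternatives were the pseudocounts 0.1 and 5, no filter and a filter at FPKM of 5, rescaling to a sum of 1000000, median-of-ratios size factors, quantile normalization, a replicate block, eBayes without trend and with the robust option, summed entries per symbol, small RNA genes kept, and each library left out in turn. Rescaling raised all values before the 1 was added, so that the added 1 weighed less and changes of low genes were less understated. The test was checked on simulated data for 12417 genes, of which 200 were changed, without a difference in scale between the groups. It recovered 3 of 50 genes changed 1.25-fold, 16 of 50 at 1.5-fold, 31 of 50 at 2-fold and 47 of 50 at 4-fold, with 5 calls among 12217 unchanged genes. In the data 8802 genes passed, so the adjusted threshold was less strict there, and these rates do not carry over to it.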

Results

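Translating ribosome affinity purification (TRAP) recovers RNA bound to ribosomes that carry a tag, here in cells in which Cre has acted on a lox allele. Here the Cre driver was Npy, the gene of neuropeptide Y, and the tissue was the amygdala of NpyCre/+;TRAPlox/lox mice. RNA was sequenced from the immunoprecipitate (IP) and from the total input, with 2 libraries per group and 3 mice pooled in each. Each of the 4 libraries listed 24490 gene entries as FPKM. The sum of FPKM was 334759 and 335119 in input replicates 1 and 2, and 423985 and 419349 in IP replicates 1 and 2. The files give no read totals. If the confidence limits listed beside each FPKM span 2 SD of a read count, they correspond to about 13200000, 13700000, 16000000 and 13500000 reads in the same order. The half-width of those limits had a median of 20.6% to 22.9% of the value at FPKM between 1 and 2, and of 7.0% to 7.6% between 10 and 20.

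The comparison of IP with input asked which transcripts were enriched on ribosomes tagged through Npy-Cre. Whether every tagged cell expressed Npy at the time of sampling was not tested. Npy was 11.8-fold higher in IP, at 1204 ± 51.7 FPKM (SD, n = 2) against 102.3 ± 4.38 in input (limma, adjusted p = 1.8e-06). The largest rises among genes above 0 in all 4 libraries were those of the neuropeptide genes Sst and Cort, ahead of Npy, followed by Pvalb, which encodes the calcium-binding protein parvalbumin, and Crhbp, which encodes a binding protein of corticotropin-releasing hormone. Most of the glial, microglial, mural and red blood cell markers tested fell, with C1ql1 rising and Gfap not past the threshold, although none of their lists passed with an estimated correlation (camera, adjusted p = 0.45 to 0.506). The nuclear long non-coding RNA Meg3 was 13.8-fold lower in IP. Npy lies on chromosome 6 from 49822729 to 49829505 (mm10, whole gene), and its log2 fold change was 3.54 (SE 0.06) on the log2(FPKM + 1) scale.

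Of 12417 genes tested with limma, 8802 passed an adjusted p of 0.05, 4597 of them higher and 4205 lower in IP. A log2 change of at least 1 on the transformed values, the 2-fold criterion, was added after the data were seen. It left 432 higher and 977 lower genes. Low genes can miss it although their mean FPKM differed by more, such as Socs3 (3.94-fold lower, log2 change -0.88). These counts rested on the settings, with 201 higher and 2214 lower after rescaling, 555 and 1610 with a pseudocount of 0.1, and 244 and 220 with a pseudocount of 5. The direction of the calls without that criterion rested on the scaling as well. With each library rescaled to a sum of 1000000, 2228 genes were higher and 6684 lower, and the median change of all genes moved from 0.02 to -0.29 on the log2 scale. Both IP values lay above or below both input values for 86.4% of the genes, where chance gives 33.3%. Across genes, which are not independent replicates, Pearson's r of the log2 values was 0.994 between the input libraries, 0.995 between the IP libraries and 0.937 to 0.939 between the groups. No library of Cre-negative tissue or of a mock precipitation was analysed here, so RNA that binds without the tag was not measured.

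**Figure D1:**
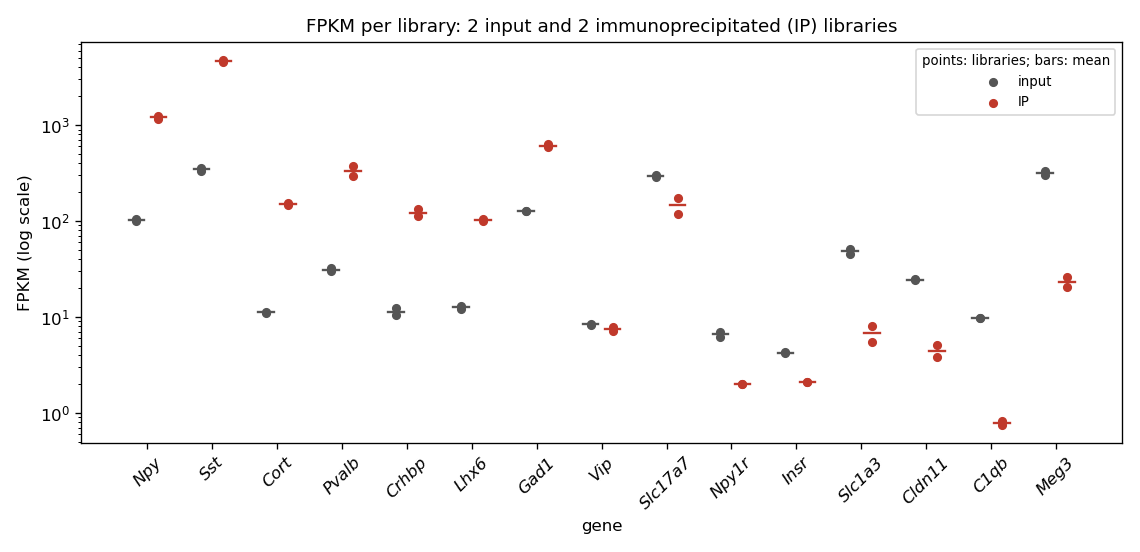
FPKM (log axis) of 15 named genes in the 2 input and 2 IP libraries; points are libraries and bars are group means. Npy, Sst, Cort, Pvalb, Crhbp, Lhx6 and Gad1 lie higher in IP, Vip differs little, and Slc17a7, Npy1r, Insr, Slc1a3, Cldn11, C1qb and Meg3 lie lower.

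Markers of GABAergic neurons rose as a group. All 12 tested genes of this list were higher in IP over all genes tested, and 12 when adjusted over the list alone, with a median log2 change of 1.94 (camera, adjusted p = 1.73e-06; adjusted p = 0.45 with an estimated correlation). Gad1, which encodes a GABA-synthesizing enzyme, increased from 127.7 ± 0.18 to 611 ± 31.1 FPKM (SD, n = 2), although reads of the overlapping Gad1os cannot be told apart from it. Lhx6, a transcription factor of interneurons from the medial ganglionic eminence, rose by 2.93 on the log2 scale. Of 12 genes known to be co-expressed with Npy or Sst, 10 rose, 0 fell and 2 did not pass, with 10 rising when adjusted over the list alone. Their median change was 1.42 (camera, adjusted p = 0.000519; adjusted p = 0.45 with an estimated correlation). After rescaling 9 of these genes were higher and 2 lower, and with quantile normalization 10 and 1. Sst rose from 346 ± 15.1 to 4659 ± 137 FPKM, a log2 change of 3.75, and Cort rose by 3.65. The remaining members with large rises were Crhbp at 3.33 and Pnoc, the gene of the peptide nociceptin, at 2.43.

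As a group, markers of other interneuron types did not rise past the threshold when set against other genes. Of 10 tested, 4 rose, 0 fell and 6 did not pass, with 4 rising when adjusted over the list alone (camera, adjusted p = 0.285, median 0.17). Fry, which compares the list with no other genes, called it upward (adjusted p = 0.0157). The median was 0.099 without input replicate 1, 0.28 without input replicate 2 and 0.29 without IP replicate 1. After rescaling the median was -0.11, with 1 gene higher and 3 lower. Pvalb was the exception in size, at 31.1 ± 1.70 FPKM in input and 336 ± 55.4 in IP (log2 change 3.39; limma, adjusted p = 1.42e-05). Tac2 changed by 0.54, a call that was lost without IP replicate 1 (adjusted p = 0.0774) or IP replicate 2 (adjusted p = 0.0516), and its change was 0.28 without input replicate 1. The Tac2 call was also lost after rescaling (0.23, adjusted p = 0.268), with quantile normalization (adjusted p = 0.0637), without the filter on FPKM (adjusted p = 0.0716) and after correction for transcript length (0.045, adjusted p = 0.814). Vip, the gene of vasoactive intestinal peptide, differed by -0.13 and Cck by 0.06, neither past the threshold.

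Most genes of glutamatergic neurons fell. Of 14 tested, 10 fell, 0 rose and 4 did not pass, with 10 falling when adjusted over the list alone (median -1.02; camera, adjusted p = 0.00267; adjusted p = 0.551 with an estimated correlation). Slc17a7, which encodes a vesicular glutamate transporter, went from 294 ± 11.3 to 145.5 ± 38.5 FPKM (log2 change -1.04; limma, adjusted p = 0.00165), and the transcription factor genes Neurod1 and Emx2 changed by -1.97 and -1.21. Among peptide and striatal-type genes of the amygdala, 5 of 17 rose, 9 fell and 3 did not pass, with the same counts of 5 and 9 when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.285). After rescaling 2 of them were higher and 10 lower. Cartpt and Tac1, both neuropeptide genes, rose by 2.30 and 1.17, while Avp, the vasopressin gene, and Trh changed by -2.46 and -1.38. Crh, the gene of corticotropin-releasing hormone, was at 2.17 ± 0.47 FPKM in input and 3.83 ± 0.55 in IP (log2 change 0.61; limma, adjusted p = 0.00728), but the call was lost without input replicate 1 (adjusted p = 0.0597), after rescaling (0.43, adjusted p = 0.0557) and after correction for transcript length (0.25, adjusted p = 0.146). Of 13 pan-neuronal genes, 8 rose, 2 fell and 3 did not pass, with 8 and 2 when adjusted over the list alone (camera, adjusted p = 0.21; median 0.23). After rescaling the median was -0.11, with 1 gene higher and 5 lower. With quantile normalization it was -0.20, with 1 higher and 8 lower, and the list passed downward (camera, adjusted p = 0.0101). Tubb3 rose by 0.76, and Eno2 by 0.40, which did not pass after rescaling (0.062, adjusted p = 0.239) and was -0.15 with quantile normalization (adjusted p = 0.0263). Map2, whose transcript is found in dendrites, changed by -1.27. Nefl changed by -0.16, a call lost without input replicate 1 (adjusted p = 0.215), input replicate 2 (adjusted p = 0.131) or IP replicate 2 (adjusted p = 0.202, change -0.093) and in 6 other settings, with adjusted p of 0.0502 to 0.102.

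Most markers of glia fell. In the astrocyte list 13 of 14 genes fell and 1 did not pass, with 13 falling when adjusted over the list alone (median -2.06, or -1.97 without the gene listed at 0; camera, adjusted p = 3.04e-06; adjusted p = 0.45 with an estimated correlation). Slc1a3, an astrocyte glutamate transporter gene, changed by -2.68, and Slc7a10 was listed at 0 in both IP libraries against 7.21 and 6.68 in input. Gfap was the gene that did not pass, at 45.02 ± 9.67 FPKM in input and 41.5 ± 12.1 in IP. All 13 oligodendrocyte genes fell, 13 when adjusted over the list alone (median -1.91; camera, adjusted p = 1.73e-06; adjusted p = 0.506 with an estimated correlation), among them Cldn11, which encodes a tight junction protein of myelin, at -2.24. Of 10 oligodendrocyte precursor genes, 9 fell and 1 rose, with 9 and 1 when adjusted over the list alone (median -1.53; camera, adjusted p = 0.00109; adjusted p = 0.506 with an estimated correlation). Sox10 and Olig1 changed by -2.31 and -2.24, and C1ql1 rose by 1.00. All 12 tested microglial genes fell, 12 when adjusted over the list alone (median -1.94; camera, adjusted p = 3.04e-06; adjusted p = 0.45 with an estimated correlation), with the complement genes C1qa and C1qb at -2.72 and -2.59. The medians of the precursor and microglial lists were -2.39 and -2.98 after rescaling, and -1.04 and -1.45 with quantile normalization.

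The vascular and blood markers that passed were all lower in IP. Of 5 tested endothelial genes, 4 fell and 1 did not pass, with 4 falling when adjusted over the list alone (median -0.84; camera, adjusted p = 0.0231; adjusted p = 0.45 with an estimated correlation). The endothelial list did not pass after rescaling (adjusted p = 0.106), with quantile normalization (adjusted p = 0.11) or without IP replicate 2 (adjusted p = 0.0538). Cldn5 and Ly6c1 changed by -1.13 and -1.12. All 6 mural cell genes fell, 6 when adjusted over the list alone (median -1.14; camera, adjusted p = 0.00168; adjusted p = 0.45 with an estimated correlation), led by Vtn at -2.68 and Myl9 at -2.24. The endothelial and mural medians were -1.55 and -1.95 after rescaling, and -0.55 and -0.71 with quantile normalization. All 3 tested globin genes of the erythrocyte list fell, 3 when adjusted over the list alone (median -3.23; camera, adjusted p = 0.0136; adjusted p = 0.506 with an estimated correlation), a call lost after rescaling (median -3.85, adjusted p = 0.0894) and without the filter on FPKM (median -1.55, adjusted p = 0.0721). Hba-a1 and Hbb-b1, at -3.45 and -3.23, share sequence with near-identical paralogs. Hba-a2 was listed at 0 in both input libraries and in IP replicate 2, but at 3.69 and 3.40 FPKM at its 2 loci in IP replicate 1. Summed over these loci the alpha-globin genes were 5.87-fold lower in IP, against 14.6-fold for Hba-a1 alone. The summed values were 32.2 and 37.4 FPKM in input replicates 1 and 2, and 8.60 and 3.25 in IP replicates 1 and 2. Hba-a1 alone was at 1.51 and 3.25 in IP, so both folds depend on single IP libraries. In the ependymal and choroid plexus list 4 of 6 genes fell and 2 did not pass, with 4 falling when adjusted over the list alone, and the list passed only with the replicate number as a block (adjusted p = 0.0196) and in 4 other settings, one of them without input replicate 2 (adjusted p = 0.00303), against 0.0529 in the unblocked camera test. Kcnj13 and Ccdc153 changed by -1.41 and -1.05. Ttr, a choroid plexus transcript, separated the pools of mice, at 172 FPKM in input replicate 1, 9.66 in input replicate 2, 10.4 in IP replicate 1 and 1.31 in IP replicate 2.

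**Figure D2:**
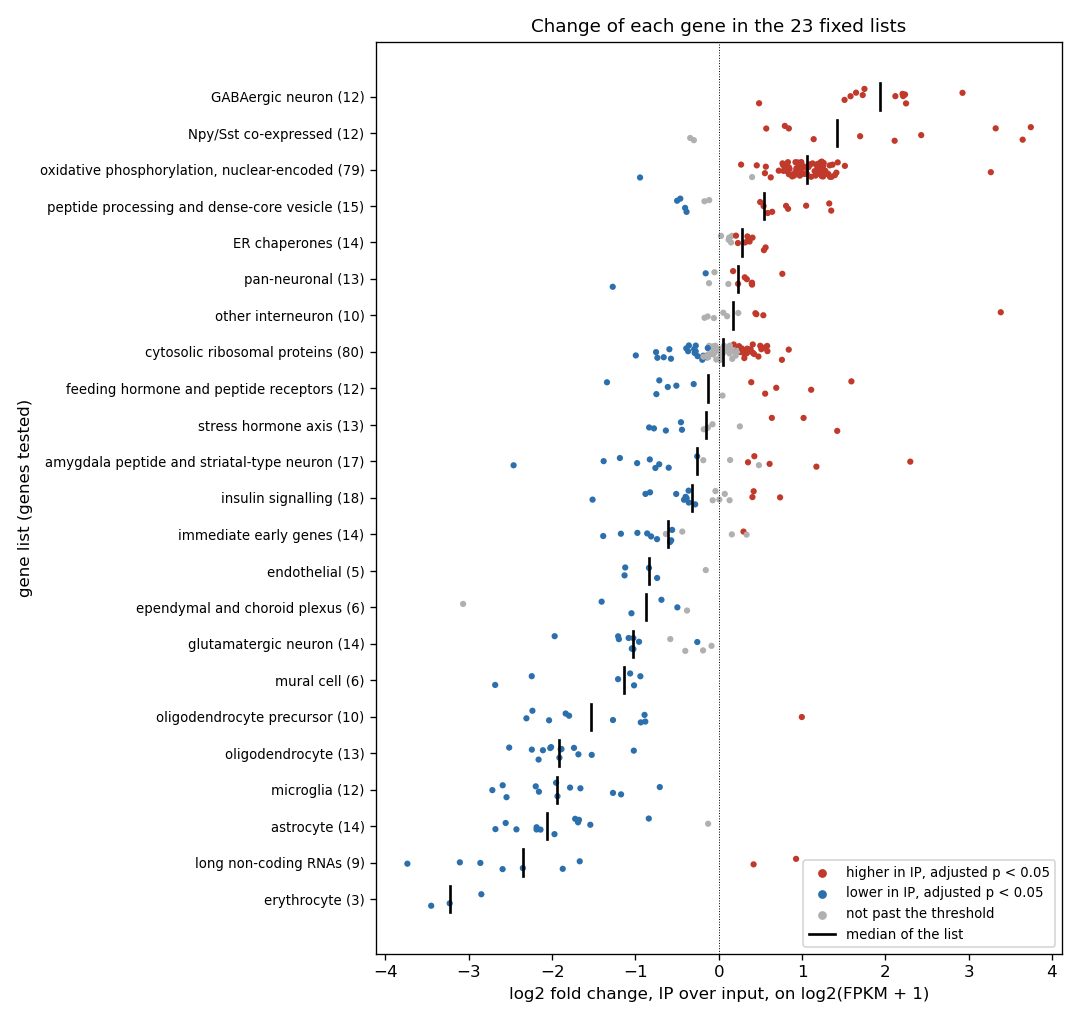
Log2 fold change of IP over input for the tested genes of the 23 fixed lists, sorted by list median; each point is a gene, coloured by its limma call, and genes listed at 0 in both libraries of a group are not drawn. GABAergic genes lie to the right with a median of 1.94, astrocyte and microglial genes to the left with medians of -2.06 and -1.94; the medians of the pan-neuronal, other interneuron, ER chaperone and ribosomal protein lists change sign under rescaling.

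The series concerns Npy neurons, stress and obesity, and receptors for feeding signals were mixed. Of 12 tested receptor genes, 5 rose, 6 fell and 1 did not pass, with 5 and 6 when adjusted over the list alone (camera, adjusted p = 0.626; median -0.13, and -0.053 without IP replicate 1 or -0.19 without IP replicate 2). Fry called this list downward (adjusted p = 0.0164). With quantile normalization 6 of its genes were higher and 4 lower (median 0.23), and after rescaling 3 and 6 (median -0.46). Npy1r, on chromosome 8 from 66697422 to 66706798, fell from 6.56 ± 0.48 to 1.98 ± 0.01 FPKM (SD, n = 2; log2 change -1.34, SE 0.09; limma, adjusted p = 5.47e-05). Insr, the insulin receptor gene, on chromosome 8 from 3150922 to 3279617, fell from 4.22 ± 0.07 to 2.10 ± 0.01 FPKM (log2 change -0.75, SE 0.08; limma, adjusted p = 0.000332). Npy5r changed by -0.61, which did not pass with quantile normalization (-0.16, adjusted p = 0.226). Npy2r was at 3.76 ± 0.21 and 3.92 ± 0.37 FPKM and did not pass (adjusted p = 0.676; change 0.046, and -0.032 to 0.123 with 1 library left out), except with quantile normalization (0.34, adjusted p = 0.0196). Ramp3 and Calcr, which encode an accessory protein of the calcitonin receptor family and the calcitonin receptor, rose by 1.59 and 1.11. Lepr, the leptin receptor gene, was below the filter, at 0.487 and 0.556 FPKM in input and 0.051 and 0.046 in IP.

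Of 18 insulin signalling genes, 10 fell, 3 rose and 5 did not pass, with 10 and 3 when adjusted over the list alone (camera, adjusted p = 0.144; median -0.32, and 0.026 after correction for transcript length). Fry called this list downward (adjusted p = 0.0138). After rescaling 1 of its genes was higher and 14 lower. Foxo1 and Socs3 changed by -1.51 and -0.88, Akt1 rose by 0.74, and Grb10 rose by 0.42, a call lost after rescaling (adjusted p = 0.335). Of 13 stress hormone axis genes, 3 rose, 5 fell and 5 did not pass, with 3 and 5 when adjusted over the list alone (camera, adjusted p = 0.441), and after rescaling 3 were higher and 9 lower. Both corticosteroid receptor genes were lower, Nr3c1 by -0.78 (14.6 ± 0.40 FPKM in input and 8.20 ± 1.73 in IP) and Nr3c2 by -0.84 on the log2 scale, while Ucn3 and Crhr2 rose by 1.42 and 1.02. Of 14 immediate early genes, 9 fell, 1 rose and 4 did not pass, with 9 and 1 when adjusted over the list alone (camera, adjusted p = 0.0888). With the replicate block that list passed (adjusted p = 0.00955), as it did without input replicate 2 (median -0.95, adjusted p = 0.0268) or without IP replicate 1 (median -1.003, adjusted p = 0.0143), with a filter at FPKM of 5 (adjusted p = 0.0229) and after correction for transcript length (adjusted p = 0.0339). Its median of -0.61 was -0.39 without IP replicate 2. Jun changed by -1.17. Npas4 changed by -1.39, a call lost without input replicate 1 (-0.94, adjusted p = 0.15) or IP replicate 2 (-0.904, adjusted p = 0.0621), without the filter on FPKM (adjusted p = 0.0643) and with the robust option (adjusted p = 0.113). Dusp1 rose by 0.30, with a value of -0.019 after rescaling and of 0.092 after correction for transcript length (adjusted p = 0.23).

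Nuclear-encoded genes of oxidative phosphorylation rose almost throughout, 77 of 79 with 1 fall and 1 not past the threshold, and 77 and 1 when adjusted over the list alone (median 1.06; camera, adjusted p = 3e-19; adjusted p = 0.45 with an estimated correlation). The median was 0.73 after rescaling, 0.64 with quantile normalization and 0.615 after correction for transcript length. Cox6a2 rose by 3.27 and Cox6b1 by 1.52, and Cox6b2 changed by -0.94, a call lost without input replicate 1 (-0.63, adjusted p = 0.0871) or with quantile normalization (-0.585, adjusted p = 0.0758). Cytosolic ribosomal protein genes went both ways, with 25 of 80 higher, 18 lower and 37 not past the threshold, or 24 and 16 when adjusted over the list alone (camera, adjusted p = 0.564). Their direction rested on the scaling. The median of 0.05 became -0.28 after rescaling, with 4 genes higher and 50 lower, and -0.03 with size factors. It was 0.088 without input replicate 1 and 0.010 without input replicate 2. With quantile normalization it was -0.31, with 6 higher and 48 lower, and the list passed downward (camera, adjusted p = 2.27e-05), as it did after correction for transcript length (-0.37, adjusted p = 4.46e-07). Rpl10a, which encodes the ribosomal protein that carries the tag in commonly used TRAP lines, rose from 89.2 ± 3.15 to 151.7 ± 3.49 FPKM (log2 change 0.76; limma, adjusted p = 6.07e-05). Whether reads of a tagged copy were counted in these values was not tested. Rpl7l1 rose by 0.84, and Rps27 and Rps19 changed by -0.995 and -0.75.

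Of 15 peptide processing and dense-core vesicle genes, 9 rose, 4 fell and 2 did not pass, with 9 and 5 when adjusted over the list alone (camera, adjusted p = 0.144). After rescaling the list passed (adjusted p = 0.0316), with 8 higher and 6 lower. Scg2 and Vgf, both granin family genes, rose by 1.35 and 1.33, and Cpe changed by -0.46. Pcsk2 changed by -0.50, a call lost without input replicate 1 (adjusted p = 0.0873) or input replicate 2 (adjusted p = 0.107), and its change was -0.30 without IP replicate 2. Of 14 ER chaperone genes, 9 rose, 0 fell and 5 did not pass, with 9 rising when adjusted over the list alone (median 0.27; camera, adjusted p = 0.0182; adjusted p = 0.551 with an estimated correlation). That list did not pass after rescaling (median -0.055 with 2 genes higher and 1 lower, adjusted p = 0.223), with quantile normalization (adjusted p = 0.227), after correction for transcript length (median 0.10, adjusted p = 0.272), with a filter at FPKM of 5 (adjusted p = 0.0778) or without IP replicate 2 (adjusted p = 0.0632). Manf and Sdf2l1 rose by 0.56 and 0.54, and Sdf2l1 did not pass after correction for transcript length (0.13, adjusted p = 0.19). Of 9 long non-coding RNAs, 7 fell and 2 rose, with 7 and 2 when adjusted over the list alone (median -2.35; camera, adjusted p = 0.0107; adjusted p = 0.553 with an estimated correlation). After rescaling the median was -2.86 with 7 lower and 1 higher, and the list did not pass (adjusted p = 0.124). Meg3 and Snhg11 changed by -3.74 and -3.11, and Peg13 rose by 0.93, although it lies within Trappc9. Snhg1 changed by 0.42, a call lost without input replicate 2 (0.255, adjusted p = 0.166) or IP replicate 2 (adjusted p = 0.116). The Snhg1 call was also lost after rescaling (0.10, adjusted p = 0.521), with size factors (adjusted p = 0.0572), with quantile normalization (adjusted p = 0.076), without the filter on FPKM (adjusted p = 0.0733) and after correction for transcript length (adjusted p = 0.0572).

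Further genes among the largest changes were Rbp4, Dlx1as and Lgals1, which rose by 2.88, 2.63 and 2.59, with Dlx1as overlapping Dlx1. Lower in IP were Ptgds, which encodes a prostaglandin D synthase, at -3.59, Igf2 at -3.27, Tmem181b-ps at -2.86, Miat at -2.86 and Hbb-bt at -2.85. Genes listed at 0 were among the largest calls and have no fold. Pcdhac2 was listed at 0 in both input libraries and at 53.8 and 56.3 in IP, Cmc1 at 0 against 25.1 and 21.95, Ak6 at 0 against 17.2 and 15.5, and Hyi at 0 against 16.5 and 16.0. Cdc42se1 was listed at 0 in both IP libraries against 30.6 and 29.4 in input, Mbd6 against 10.5 and 9.54, Usp16 against 9.42 and 8.57, Elac2 against 8.67 and 8.90, and Pltp against 8.69 and 7.57. All 51 genes listed at 0 in both libraries of one group overlap another listed gene, against 20% of the other genes tested, and Rpl26 and Ndufs5, which cells generally express, were listed at 0 in all 4 libraries. A listed 0 can therefore be a failed estimate.

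Change also followed transcript length. From the shortest to the longest of 5 groups of about equal numbers of genes, the median log2 change was 0.39, 0.17, 0.04, -0.08 and -0.33, and Spearman's rho across genes was -0.37. Npy, Sst and Pvalb have transcripts of 566, 721 and 977 nt, and Insr one of 9355 nt. With that trend removed, an alternative chosen after the data were seen, Sst stood at 3.21, Pvalb at 2.93, Npy1r at -1.39 and Insr at -0.30 (limma, adjusted p = 0.0138).

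**Figure D3:**
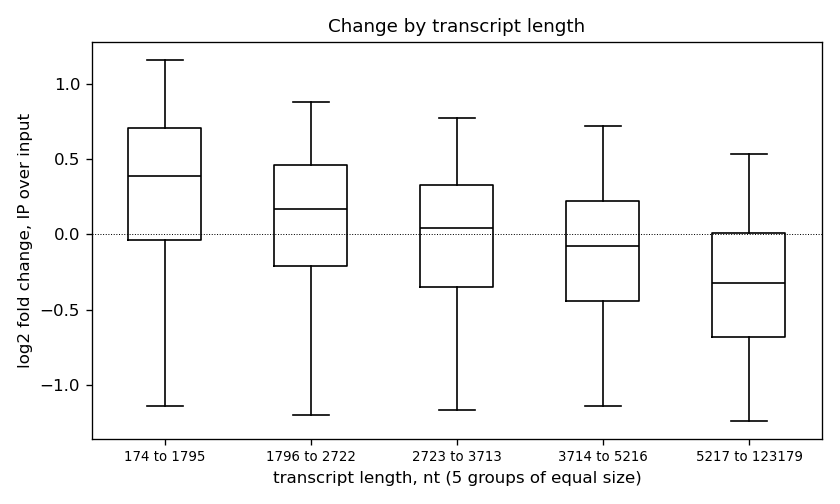
Log2 fold change of IP over input by transcript length in nt, in 5 groups of about equal numbers of genes; boxes show quartiles, centre lines medians and whiskers the 5th to 95th percentiles of genes. The median goes from 0.39 in the shortest group to -0.33 in the longest.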

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

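The settings without genes listed at 0, with the correction for length and with the 2-fold criterion were chosen after the data were seen. Npy stayed higher in IP and past the threshold in every setting, with a log2 change of 2.96 to 3.59 and adjusted p up to 0.00418. Of 89 named genes tested, 75 kept their call and direction under every alternative in which they were tested. The count of 8802 calls became 1409 with the 2-fold criterion, 9114 with the replicate block and 7145 to 8221 with 1 library left out, where the lone library of a group is assumed to vary like the others. Genes higher in IP numbered 2228 after rescaling to a sum of 1000000, and genes lower numbered 6684. This setting centres the genes lower by construction and also gives the added 1 less weight, and the 2 effects were not separated. With a filter at FPKM of 5, 9011 genes were tested, of which 4207 were higher and 2437 lower. Their median change was 0.144, so the genes removed were more often lower in IP. Lists past the threshold numbered 0 with an estimated correlation and 11 to 15 with 1 library left out. The pairing by pools changed 2 list calls, those of the ependymal and choroid plexus list (adjusted p = 0.0196) and of the immediate early genes (adjusted p = 0.00955), and no call of a named gene. The replicate correlations moved to 0.988 (input) and 0.989 (IP) with a pseudocount of 0.1, and to 0.993 (input) and 0.993 (IP) with a filter at FPKM of 5. Among named genes with a call the sign changed for Eno2 with quantile normalization (-0.15) and for Dusp1 after rescaling (-0.019, not past the threshold). List medians changed sign after rescaling (pan-neuronal -0.11, other interneuron -0.11, ER chaperones -0.055, ribosomal proteins -0.28), with size factors (ribosomal proteins -0.03), with quantile normalization (pan-neuronal -0.20, ribosomal proteins -0.31, feeding receptors 0.23), without a filter (feeding receptors 0.046) and after correction for length (ribosomal proteins -0.37, insulin signalling 0.026). The cause was not tested. Depth limits genes at low FPKM. In simulated data with 200 changed genes, 16 of 50 changes of 1.5-fold were found, a rate that does not carry over to data with 8802 calls.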

Other observations

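The gene families in this part were chosen after the data were seen, and so were the tests of other interneuron markers, of parvalbumin neuron genes, of carry-over from input, of each receptor gene alone and with libraries as units. The bound for the parvalbumin neuron genes was changed after their result was seen, from random lists to the GABAergic list, and that for carry-over likewise, from a permutation p to a 95% interval over the libraries and then to the SD between pools. The parvalbumin gene list was written after Rbp4 and Cplx1 had been seen. The permutation test of length and level for the glutamatergic genes and the joint test of the 3 receptor genes were set before their results were seen.

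All 35 tested proteasome subunit genes rose (median 0.52; camera, adjusted p = 3.67e-08 over the 10 families; adjusted p = 0.555 with an estimated correlation), with 22 higher after rescaling (median 0.19) and 22 with quantile normalization (median 0.21). Of 20 cytosolic aminoacyl-tRNA synthetase genes, 14 rose, 1 fell and 5 did not pass (median 0.37; camera, adjusted p = 0.00218; adjusted p = 0.555 with an estimated correlation), with Gars at 0.93; after rescaling 7 were higher and 5 lower (median 0.043), and with quantile normalization 9 and 1 (median 0.18). Of 13 collagen genes, 11 fell, 1 rose and 1 did not pass (median -1.04; camera, adjusted p = 0.000735; adjusted p = 0.555 with an estimated correlation). The collagen median was -1.86 after rescaling and -0.46 with quantile normalization. Col6a1 changed by -1.99 and Col4a1 by -1.52, and Col25a1 rose by 0.78. No change corrected for transcript length is given for these families. Among all genes the shortest of 5 length groups had a median of 0.385, so how far length accounts for the family changes was not tested.

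Subunits of one channel or receptor family moved apart. Of 40 voltage-gated potassium channel genes, 13 rose, 20 fell and 7 did not pass, and Kcnip1, Kcns3, Kcnab3 and Kcnc2 rose by 2.54, 1.89, 1.87 and 1.80. Of 16 ionotropic glutamate receptor genes, 6 rose and 9 fell, with Grik1 and Gria4 at 1.402 and 0.99, and Grin2c and Gria2 at -1.67 and -1.14. Of 12 GABA-A receptor genes, 4 rose and 5 fell, with Gabra2 at -1.34. The balance rested on the scaling in part: the potassium channel genes were 8 higher and 24 lower after rescaling and 15 and 14 with quantile normalization, and the GABA-A genes 1 and 6 or 3 and 5. None of these 3 families passed as a group (camera, adjusted p = 0.685, 0.685 and 0.824). Nxph1 and Nxph2, which encode neurexophilins, rose by 2.57 and 2.07, and Cbln4 rose by 1.36. Of 9 serotonin receptor genes 4 rose and 2 fell, of 12 MHC genes 6 rose and 5 fell, of 17 neurexophilin and neurexin partner genes 5 rose and 7 fell, and of 286 Zfp genes 53 rose and 95 fell; these families did not pass either (camera, adjusted p = 0.666, 0.941, 0.941 and 0.302). After rescaling the serotonin receptor genes were 1 higher and 2 lower, the MHC genes 2 and 5, the neurexophilin and partner genes 3 and 9, and the Zfp genes 14 and 165. With quantile normalization these counts were 6 and 0, 6 and 3, 6 and 6, and 120 and 42 in the same order. Between the pools of mice, 12 of 14 immediate early genes were higher in replicate 1 than in replicate 2 in both IP and input, against 28.9% of all genes.

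Pvalb rose with Npy and Sst, although parvalbumin neurons are usually described as a class apart. Enrichment of every interneuron type alike is argued against only as far as 6 markers of other types go (Vip, Cck, Calb2, Htr3a, Cnr1 and Lamp5). They belong to the other interneuron list, already seen to change little, so this is no independent test. Their median change lay 1.79 below that of the GABAergic list (1.84 with libraries as units, SE 0.026, beyond its 95% interval over the libraries). An exact permutation of the libraries gave p = 0.333, the smallest possible with 2 per group. Expression of these markers in other cells was not tested. An effect at the Pvalb locus alone cannot be told apart. The median change of 20 genes typical of parvalbumin neurons (1.36; 18 rose, 2 fell) lay above the 95th percentile of random lists matched on FPKM (0.271), as did that without Rbp4 and Cplx1 (1.26 against 0.244), but it differed by -0.572 from that of the GABAergic list, so a rise of GABAergic genes in general may account for it. RNA bound without the tag in proportion to input would pull Pvalb towards its input level. Such binding would raise no gene above its input level. The 10.8-fold rise of Pvalb, a gene picked because it rose, is therefore no test of it. Tagged ribosomes in parvalbumin cells, Pvalb expression within Npy or Sst cells, and uneven binding of untagged RNA were not tested and stay open.

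By list median, glutamatergic genes fell less than astrocyte, oligodendrocyte and microglial genes. Single members differed. Neurod1 and Emx2 had IP to input ratios of mean FPKM of 0.163 and 0.1455, within the range of the glial list medians, while 4 of 14 members did not pass. Carry-over of input RNA by 1 share for every gene would by itself give equal IP to input ratios. The median ratio of the glutamatergic list was 0.575 and 0.425 in the 2 pools against 0.079 to 0.244 in the astrocyte, oligodendrocyte and microglial lists, a gap of at least 0.181 where the SD between pools was at most 0.106. That bound was set after the 95% interval over the libraries had not been passed, so the gap gives no verdict on carry-over. Ratios also differed among the glial lists, at 0.079 and 0.086 in the microglial list and 0.177 and 0.244 in the oligodendrocyte list. Over genes, transcript length and level are argued against as the cause of the difference between the lists. The difference was 1.124 times its value after subtracting the change of matched genes (1.149 and 1.492 times in the 2 pools, permutation p = 0.00016). That p and those for the ratios (1e-05, the smallest that 100000 permutations can give, and 0.00017) treat genes as independent. Over the libraries neither the difference (0.915, SE 0.343) nor the matched one (1.141, SE 0.298) lay beyond its 95% interval. With libraries as units the difference is thus not established, and the reading on length and level rests on genes and on the 2 pools. Tagging of glutamatergic cells and uneven binding of untagged RNA were not tested and stay open.

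The receptor genes Insr, Igf1r and Npy1r were lower in IP, and long transcripts were lower in general. The joint test did not settle whether length accounts for them, since 1 of the 3 lay below the 5th percentile of the 200 genes nearest in length and level. The reading of each gene alone was set after these percentiles had been seen. Npy1r lay at percentile 4.5 and stayed at -1.39 after correction for length, which argues against length as its whole cause, though by a narrow margin; Igf1r lay at percentile 48.5, and its change went from -0.71 (SE 0.09) to -0.17 (SE 0.08, limma, adjusted p = 0.113) after correction, where the smaller size ended the call, so length may account for it. Insr lay at percentile 34.0 but was still called after correction (-0.30, adjusted p = 0.0138), and whether length is its cause cannot be told apart from a cell type difference here.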
